A study of Mus musculus with 2 samples.

How the data were processed

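Single-cell RNA sequencing was analysed for 2 droplet libraries of mouse aorta, 1 from wild-type mice and 1 from knock-in mice that carry a mutated matrix Gla protein (MGP). Per the labels' protocols, the mice were 1 month old, males and females were used, the adventitia was dissected away under a microscope, and the aortas were digested with Liberase. Dead cells stained with DAPI were removed by flow cytometry, per the labels, and the libraries followed the 10x Genomics instructions. Both libraries carry the same batch label. The mutated residue, the number of mice per library and the time of day at collection were not given in the sources used here.

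The deposited values are UMI counts (unique molecular identifiers, 1 per captured RNA molecule) per gene and barcode, made by the authors with Cell Ranger 7.1.0, per the file headers and the submitters' processing notes. They are raw counts over all barcodes with no cell filter: 1307634 barcodes in the wild-type and 1421297 in the knock-in library, over 32285 genes. The genome build and annotation were not given in the sources used here, so no coordinates are printed. The order of genes around Mgp was taken from the GENCODE vM21 annotation.

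Cells were barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrially encoded UMIs. Doublets were scored per library with scrublet in scanpy 1.11.5, and the highest-scoring 0.8% per 1000 cells were removed, which took out 109 wild-type and 330 knock-in cells. Scrublet's automatic threshold would have called 4 and 120 cells. Both libraries were clustered together without integration: counts per 10000, log transformation, 2000 variable genes without mitochondrial, ribosomal, hemoglobin and sex-linked genes and Mgp, 30 principal components, 15 neighbours and Leiden resolution 0.5 with igraph 0.11.9. The analysis ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

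Clusters were named from 21 marker lists fixed before the data were examined. The scoring rule was not fixed then: 2 rules were tried on the clusters with the class shares of both libraries in view. The rule kept scores each list by the mean log2 gain of its markers over the cluster where each is lowest. It leaves a cluster unnamed when another list reaches more than 0.65 of the best score, a limit first set at 0.6 and raised after the clusters were seen. Both limits gave the same names at the resolution used. They differ at resolution 1.0, where the limit of 0.6 left 25.9% of wild-type and 9.12% of knock-in cells unnamed.

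UMIs were summed per library and class and expressed as CPM of the total UMIs of the same cells. With 1 library per genotype no test between genotypes was possible, so no p-value is given. Sums carry exact Poisson intervals, log2 ratios of knock-in over wild-type carry exact conditional binomial intervals, and shares carry Clopper-Pearson intervals, all at 95%. These intervals cover counting error only, not differences between mice, dissections or libraries. For a count of 0 the floor was 3 counts per library. Folds against this floor leave out the counting error of the other library.

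The rule for named genes, fixed before the data were examined, covered SMC-like, fibroblast-like and endothelial-like classes with at least 100 cells in each library. Macrophage or monocyte-like cells were not among the classes it covered. It asked for at least 50 UMIs over both libraries, at least 20 CPM in 1 or both, and, in the library where the gene is higher, a level at least 1/5 of that of the class with the highest level. Mitochondrial, ribosomal, hemoglobin, immunoglobulin, sex-linked and unnamed gene models were left out. The 12 highest and 12 lowest genes were ranked by the interval bound nearest 0. Endothelial-like cells were too few for this rule. Some genes that the rule selects are not reported here. From 25 gene lists fixed at the same time, 2 to 4 members with the most UMIs or the largest ratio were also named. Id4, Smad6, Bambi, Lox, Ltbp4, Fbn1, Fbln5, Ogn, Notch3, mt-Nd4 and mt-Cytb in SMC-like cells, and Chrd, Vcam1, Ltbp4, Igf2 and mt-Nd4 in fibroblast-like cells, lie outside that rule and were chosen after their values were seen, as were all genes named in endothelial-like and macrophage or monocyte-like cells.

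For each list, the median log2 ratio of members with at least 10 UMIs over both libraries was taken, with 0.5 added to each sum. Within a subset of cells this minimum was applied anew, so such a median can rest on fewer members. It was placed among 10000 random lists of the same size matched on mean expression. This percentile describes these libraries and is not a test. Lists of imprinted growth genes and of clock genes were added after data had been seen. The steps were tested on simulated counts: of 200 genes changed by 1 or 2 on the log2 scale, 100% had intervals that left out 0 in SMC-like cells (5880 genes) and in fibroblast-like cells (6127 genes). Intervals left out the simulated true ratio for 4.54% and 4.91% of the unchanged genes. These counts were Poisson draws from a pooled profile, so they check counting error only and not differences between real libraries.

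The alternatives tried were other limits on UMIs, genes and mitochondrial share, no doublet removal, Leiden resolution 1.0, separate clustering, median-of-ratios scaling, equal weight per cell, subtraction of free RNA, a lower count minimum, and female or male cells alone. Female cells had an Xist UMI and no UMI of a Y-linked gene, and male cells the reverse. Free RNA was profiled from barcodes with 10 to 100 UMIs, and its share was estimated from hemoglobin UMIs at 2.75% in wild-type and 1.20% in knock-in cells, on only 37 and 24 hemoglobin UMIs in SMC-like, fibroblast-like and endothelial-like cells together. Macrophage genes outside macrophages gave 0.760% and 0.850%, and matrix genes in macrophages 1.88% and 1.34%. Cells of 8000 to 20000 UMIs, the largest cluster of a class, cells with or without a UMI of a posterior Hox gene, and the first naming limit were alternatives chosen after seeing the data.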

Results

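Cells of the aorta from 1-month-old wild-type mice and from mice with a mutated MGP were compared by single-cell RNA sequencing. MGP is a secreted protein that inhibits calcification and binds bone morphogenetic proteins (BMPs), and the study asks how mutating it bears on BMP-regulated differentiation of cells in the aortic media. Each genotype is represented by 1 library, so no difference below has a replicate check. The wild-type library held 79626104 UMIs and the knock-in library 85831737. After filtering, 3588 wild-type cells with a median of 20395.5 UMIs and 6089 knock-in cells with a median of 11650 UMIs were kept. Median mitochondrial shares were 1.87% and 3.07%. Female cells made up 32.6% of the wild-type and 46.0% of the knock-in cells, and male cells 56.7% and 33.5%.

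Mgp (ENSMUSG00000030218), the gene altered by the knock-in, was transcribed in both libraries. Its UMIs do not tell the mutated from the wild-type transcript, so they show only that the gene is expressed. Levels are given as CPM, the UMIs of a gene scaled to the total UMIs of the same cells. Over all cells Mgp stood at 7385 CPM in the wild-type library and 8222 CPM in the knock-in library, a log2 ratio of 0.15 (95% counting interval 0.15 to 0.16). The ratio was 0.40 in SMC-like cells, where levels were 5246 and 6911 CPM, 0.31 in fibroblast-like cells and 0.40 in endothelial-like cells. Macrophage or monocyte-like cells held 101 and 98.4 CPM, with a ratio of -0.04 (-0.24 to 0.15). Within male cells alone the ratio was -0.04 over all cells and -0.02 in fibroblast-like cells, against 0.17 and 0.48 within female cells. In SMC-like cells it was 0.31 within male and 0.42 within female cells.

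The knock-in library held a much larger share of smooth muscle cell (SMC)-like cells and a smaller share of fibroblast-like cells. SMC-like cells, most of them in a cluster led by Mylk4, Npnt, Sost and the contractile genes Myh11, Acta2 and Cnn1, made up 8.22% of wild-type cells (295 of 3588, interval 7.34 to 9.17) and 42.6% of knock-in cells (2592 of 6089, 41.3 to 43.8). Fibroblast-like cells, in 3 clusters with Serpinf1, Fmod or Cd248 among the leading genes, made up 75.2% (2697 cells, 73.7 to 76.6) and 47.8% (2911 cells, 46.5 to 49.1). Endothelial-like cells, led by Cytl1, Ptprb, Vwf, Pecam1 and Egfl7, made up 1.78% (64 cells, 1.38 to 2.27) and 0.755% (46 cells, 0.554 to 1.01). Macrophage or monocyte-like cells, with Lyz2, C1qa, C1qb, Mrc1 and C1qc among the leading genes, made up 9.78% and 4.80%. Mesothelial-like cells, with Upk3b and Msln among the leading genes, were 8 in the wild-type library and 0 of 6089 in the knock-in library, whose interval reaches 0.0606%.

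SMC-like cells were more frequent in the knock-in library within each sex, at 54.3% against 9.85% of female cells and 37.5% against 7.47% of male cells. Cells with neither Xist nor Y-linked UMIs made up 8.64% of wild-type and 18.8% of knock-in cells and are left out of this split. SMC-like cells were 6.77% of these cells in the wild-type and 22.3% in the knock-in library. Fibroblast-like cells were split differently among their clusters. The largest, led by Pex5l, Fmod and Ccn5, held 1366 wild-type and 1284 knock-in cells (38.1% and 21.1% of kept cells). A cluster led by Tmem100, Opcml and Ly6c1 held 771 and 453 (21.5% and 7.44%), and a cluster of lower depth, led by Entpd2 and Cpz, held 560 and 1174 (15.6% and 19.3%). These shares can reflect dissection, digestion and the live-cell sort as well as the tissue, and the libraries differ in depth. With separate clustering the difference in fibroblast-like cells was -16.5 percentage points, and at resolution 1.0 with the first naming limit -12.2, against -27.4 in the setting used elsewhere. Unnamed clusters held 4.82% of wild-type and 4.07% of knock-in cells in the latter, 15.2% and 3.83% with separate clustering, and 25.9% and 9.12% at resolution 1.0 with the first naming limit. A cycling cluster led by Prc1, Ube2c, Cenpf and Top2a held 110 wild-type and 27 knock-in cells. A cluster with pericyte and SMC markers, with Rgs5 among its leading genes, held 56 and 189.

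**Figure D1:**
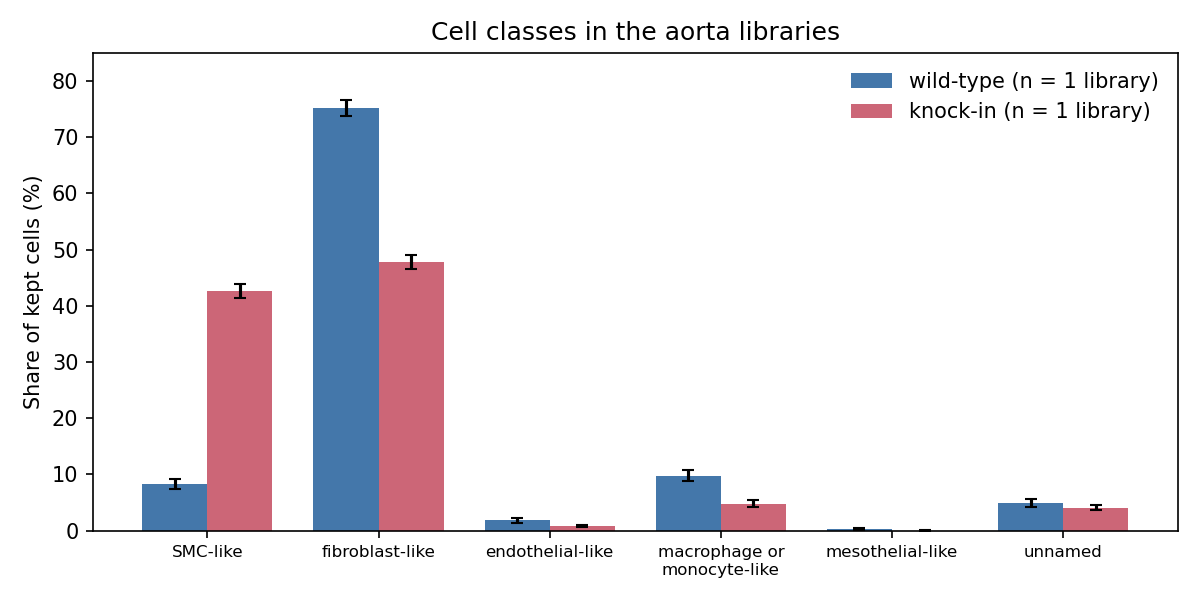
Share of kept cells (%, linear axis from 0) in each cell class, for the wild-type library (blue) and the knock-in library (red), 1 library each. Error bars are 95% Clopper-Pearson intervals of counting error, and SMC-like cells stand at 8.22% and 42.6%.

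In SMC-like cells, the contractile cells of the media, genes of the circadian clock were among those with the largest ratios between the libraries. Dbp, a clock-controlled transcription factor, was 21.1-fold higher in the knock-in library (11.2 against 238 CPM; log2 ratio 4.40, 4.05 to 4.79). Its relatives Hlf (2.89) and Tef (2.28), the period gene Per3 (2.68) and the clock repressors Nr1d2 (2.15) and Nr1d1 (1.84) were higher too. Arntl, which encodes the core clock activator BMAL1, was lower (29.2 against 2.20 CPM; -3.72, -4.14 to -3.32), as was Npas2, which encodes a binding partner of BMAL1 (-2.37). Dbp stood at 5.06 in the largest SMC-like cluster, and Arntl at -3.13 in cells with a UMI of a posterior Hox gene.

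Tcap, which encodes a sarcomeric Z-disc protein and is known as a clock-controlled gene in heart, was 15.5-fold higher in knock-in SMC-like cells (30.1 against 467 CPM; 3.95, 3.74 to 4.18). Tafa1 (2.18), a secreted chemokine-like protein, and the phosphatase gene Ppm1n (2.10) were higher. Igfbp2, which encodes an insulin-like growth factor binding protein, was lower (78.6 against 15.5 CPM; -2.34, -2.53 to -2.16). The cell-cycle inhibitor Cdkn1a (-1.57), the metalloprotease Adamts12 (-1.91), the forkhead factor Foxs1 (-1.77), the cadherin Cdh11 (-1.62), the tendon transcription factor Scx (-1.45), the mitochondrial folate enzyme Mthfd2 (-1.50), Cdk2ap1 (-1.55) and Wdr95 (-1.74) were lower. Hist2h2aa1 (2.78), Wdr89 (2.02) and Eif3j2 (-2.27) have near-identical copies that can share reads, so their values are uncertain. In cells of 8000 to 20000 UMIs Adamts12 stood at -0.90 and Scx at -0.86, Tafa1 stood at 1.46 in female and 3.38 in male cells, and Igfbp2 at -1.66 in the largest SMC-like cluster. Ppm1n stood at 3.05 in cells of 8000 to 20000 UMIs and Tcap at 3.25 in cells with a posterior Hox UMI. Hist2h2aa1 stood at 4.31 in female cells, on only 2 wild-type UMIs. Of 6223 genes at the count minimum, 124 were at least 2-fold apart, 66 higher and 58 lower. A lower count minimum gave 1758 such genes, 929 higher and 829 lower. The median over all genes was -0.05.

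**Figure D2:**
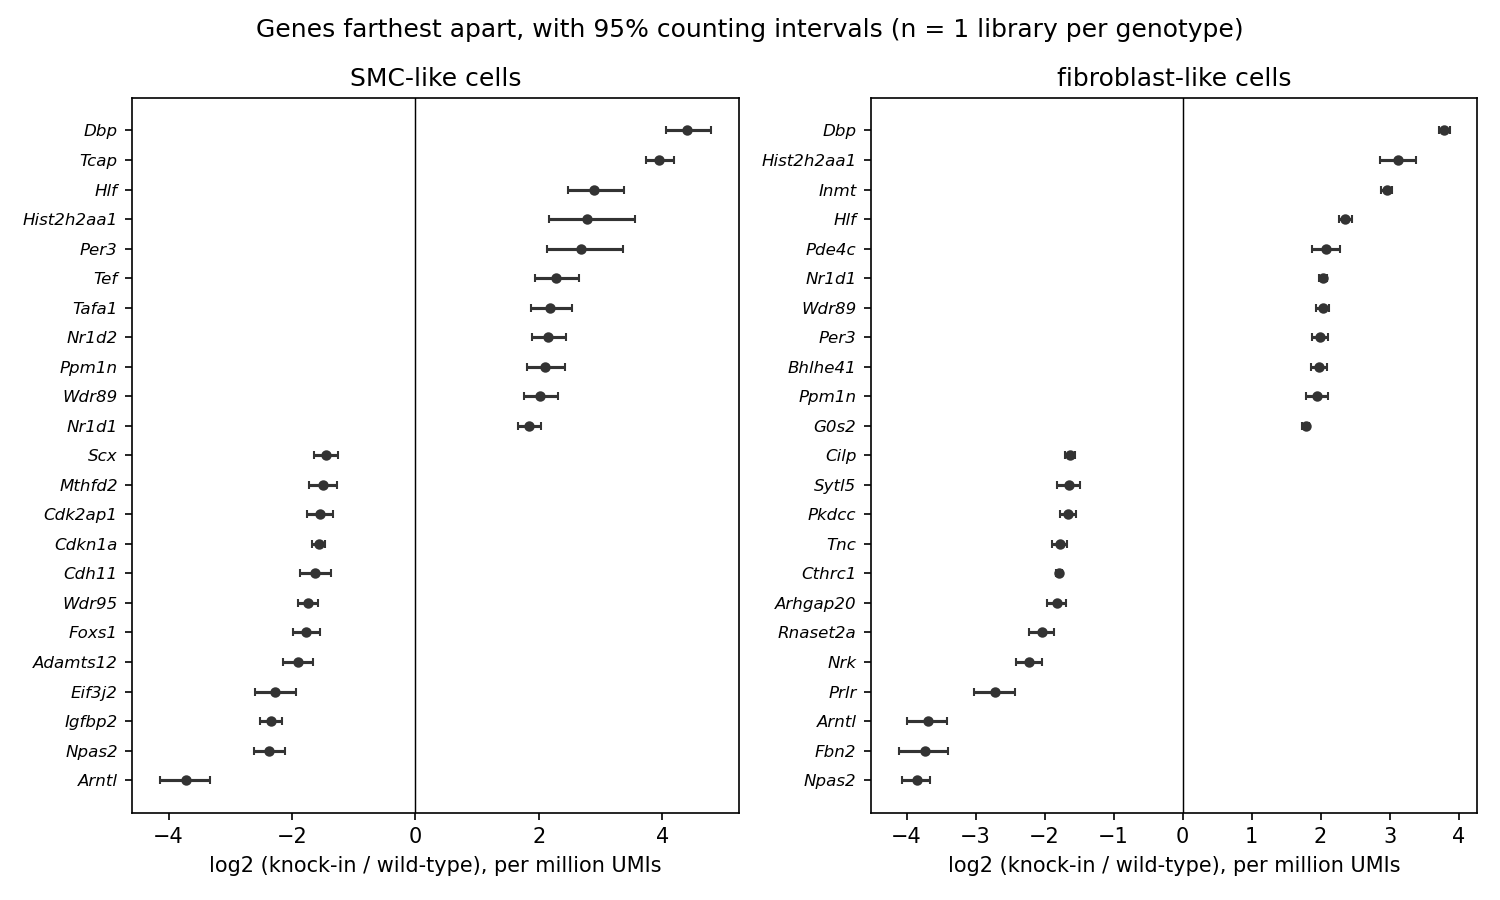
Log2 ratio of knock-in over wild-type CPM for the named genes with the highest and lowest ratios in SMC-like cells (left) and fibroblast-like cells (right), 1 library per genotype. Points are ratios, bars are 95% counting intervals, and the horizontal scales of the panels differ; Dbp is highest in both panels, at 4.40 and 3.80.

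BMP target genes were higher as a group in knock-in SMC-like cells. Of 12 listed genes 11 were measured: 4 were at least 1.5-fold higher, 0 were 1.5-fold lower and 7 lay between. Their median log2 ratio was 0.49, at percentile 100 among matched random lists, 95% of which lay between -0.25 and 0.18. The BMP-responsive factor Atoh8 stood at 0.78 and Smad9, which encodes a SMAD activated by BMP receptors, at 0.87. The inhibitory SMAD genes Smad7 and Smad6 stood at 0.70 and 0.53. Smad7 stood at 0.90 in female and 0.22 in male cells, and Smad6 at 0.71 and 0.31 (-0.03 to 0.68). Smad9, on 14 and 16 wild-type UMIs, stood at 0.60 (-0.13 to 1.55) in female and 0.90 (0.17 to 1.80) in male cells. Among the inhibitors of differentiation, classical BMP targets, Id4 stood at 0.49, Id1 at 0.29 and Id2 at 0.13, and Id3 at -0.03 (-0.08 to 0.01). The BMP pseudoreceptor gene Bambi stood at -0.18, and at 0.05 in male cells. The list median was 0.13 (0.06 to 0.56) in cells with a UMI of a posterior Hox gene, 89 wild-type and 506 knock-in cells, and 0.47 in cells without one. Posterior Hox genes, which mark position along the body axis, were themselves lower in knock-in SMC-like cells (list median -1.42, Hoxc10 -3.71, Hoxa10 -2.77, Hoxa9 -1.42, on 20, 17 and 24 wild-type UMIs). In the largest SMC-like cluster Hoxa9 stood at -0.67.

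BMP ligands and receptors had a median of 0.14 (percentile 96.6), with the type II receptor gene Bmpr2 at 0.35. BMP antagonists had a median of -0.11, or 0.19 in cells of 8000 to 20000 UMIs and 0.26 in male cells, with Sost, which also inhibits Wnt signalling, at 0.56 and Twsg1 at 0.56. Follistatin, encoded by Fst, stood at -1.19, and at 0.04 without doublet removal. TGF-beta target genes had a median of -0.13. Among them Smad7 (0.70) was higher, and the matricellular gene Ccn2 (-0.42), Pmepa1 (-0.43) and Col1a1 (-0.90) were lower. Notch pathway genes had a median of 0.36 (percentile 99.8). Hes1, Notch2 and Rbpj were at least 1.5-fold higher and 1 member was lower, and 2 further members with higher ratios rest on 0 and 1 wild-type UMIs, the former at least 1.32-fold higher. The Notch target Hes1 stood at 0.93, the receptors Notch2 at 0.67 and Notch3 at -0.46, and the effector Rbpj at 0.59. The Notch median was 0.07 in cells of 8000 to 20000 UMIs.

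Contractile genes had similar levels in SMC-like cells of both libraries. Of 17 measured, 1 was at least 1.5-fold higher (smoothelin, Smtn, 0.87), 0 were lower and 16 lay between. The median was 0.10, at percentile 87.8, and -0.02 in cells of 8000 to 20000 UMIs. Myh11, smooth muscle myosin, stood at 0.41, the SMC master regulator Myocd at 0.24, Acta2 at -0.20, Tagln at -0.11 and Ldb3 at -0.35. Genes of modulated SMCs had a median of -0.12, with 2 of 15 at least 1.5-fold higher and 4 lower. The adhesion molecule Vcam1, 1 of the higher members, stood at 1.49, or 0.85 in male cells.

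The chondro-osteogenic list had a median of 0.41 (percentile 97.2) over 11 measured genes, and 0.05 when the libraries were clustered separately. Spp1 and Cytl1 were at least 1.5-fold higher and 1 member was lower, while a member with 0 wild-type and 10 knock-in UMIs lies under the floor and has no fold. Osteopontin, encoded by Spp1, had 0 wild-type and 57 knock-in UMIs, which is 3.14-fold higher with the 0 set to the floor, counting error aside. The cartilage matrix gene Comp stood at 0.41, and at -0.15 in male cells. Aggrecan, encoded by Acan, stood at -0.32, and at 0.36 in the largest SMC-like cluster. Cytl1, on 5 and 100 UMIs, stood at 1.59, and at -0.96 in female cells. It is also the leading gene of the endothelial-like cluster, at 3412 CPM there, so UMIs from endothelial cells are not ruled out. Calcification regulators had a median of 0.40 (percentile 99.8), with 2 of 9 measured genes at least 1.5-fold higher and 7 between. That median is the ratio of Mgp itself, and the list also holds Enpp1 (0.62) and Ank (0.42), a pair acting in the supply of pyrophosphate, an inhibitor of mineral growth.

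Elastic fibre genes were lower as a group in knock-in SMC-like cells. Of 15 measured, 7 were at least 1.5-fold lower and 1 was higher, with a median of -0.39 (percentile 0.01). Elastin, encoded by Eln, stood at 19190 CPM in wild-type and 8720 in knock-in cells (-1.14, -1.15 to -1.13). The cross-linking enzyme gene Lox (-1.04) and the microfibril genes Mfap2 (-1.07) and Mfap4 (-0.60) were lower, while Fbln5 stood at -0.24 and Fbn1 at -0.17. Ltbp4, which encodes a latent TGF-beta binding protein, stood at 0.70. Collagens and proteoglycans had a median of -0.20 (percentile 1.25), with Col1a1 at -0.90, Col1a2 at -0.65, Col3a1 at -0.20, Ogn at 0.54 and Prelp at 0.96. Decorin, encoded by Dcn, stood at -1.02, with 0.51 in female and -1.87 in male cells, and -0.06 in cells of 8000 to 20000 UMIs. The estimated free RNA exceeded its UMIs in both libraries, so background is not ruled out for Dcn in SMC-like cells. Fibroblast markers were lower in the same cells (median -0.88), and so were macrophage markers (-0.55).

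Mitochondrially encoded genes were higher in knock-in SMC-like cells (median 0.49, percentile 100), taking 4.59% of UMIs against 3.31%. The values were uneven, with mt-Nd3 at 1.66 but mt-Nd4 at 0.18 and mt-Cytb at 0.18. Other list medians in SMC-like cells were 0.21 for hypoxia genes, -0.16 for dissociation stress, -0.26 for inflammatory genes, -0.28 for interferon response, -0.11 for the Wnt pathway (-0.69 in male cells; the secreted Wnt modulator Sfrp2 -1.02), -0.22 for progenitor genes, -0.10 for mesenchymal transition, -0.05 for endothelial identity and -0.01 for anterior Hox genes. The endothelial identity median was 0.70 in cells with a posterior Hox UMI, where the progenitor median was -0.83. Cardiac outflow genes had a median of 0.03 over 4 measured genes, but 1.57 (0.84 to 2.55) in female and -0.28 in male cells. The medians within 1 sex can rest on fewer members.

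**Figure D3:**
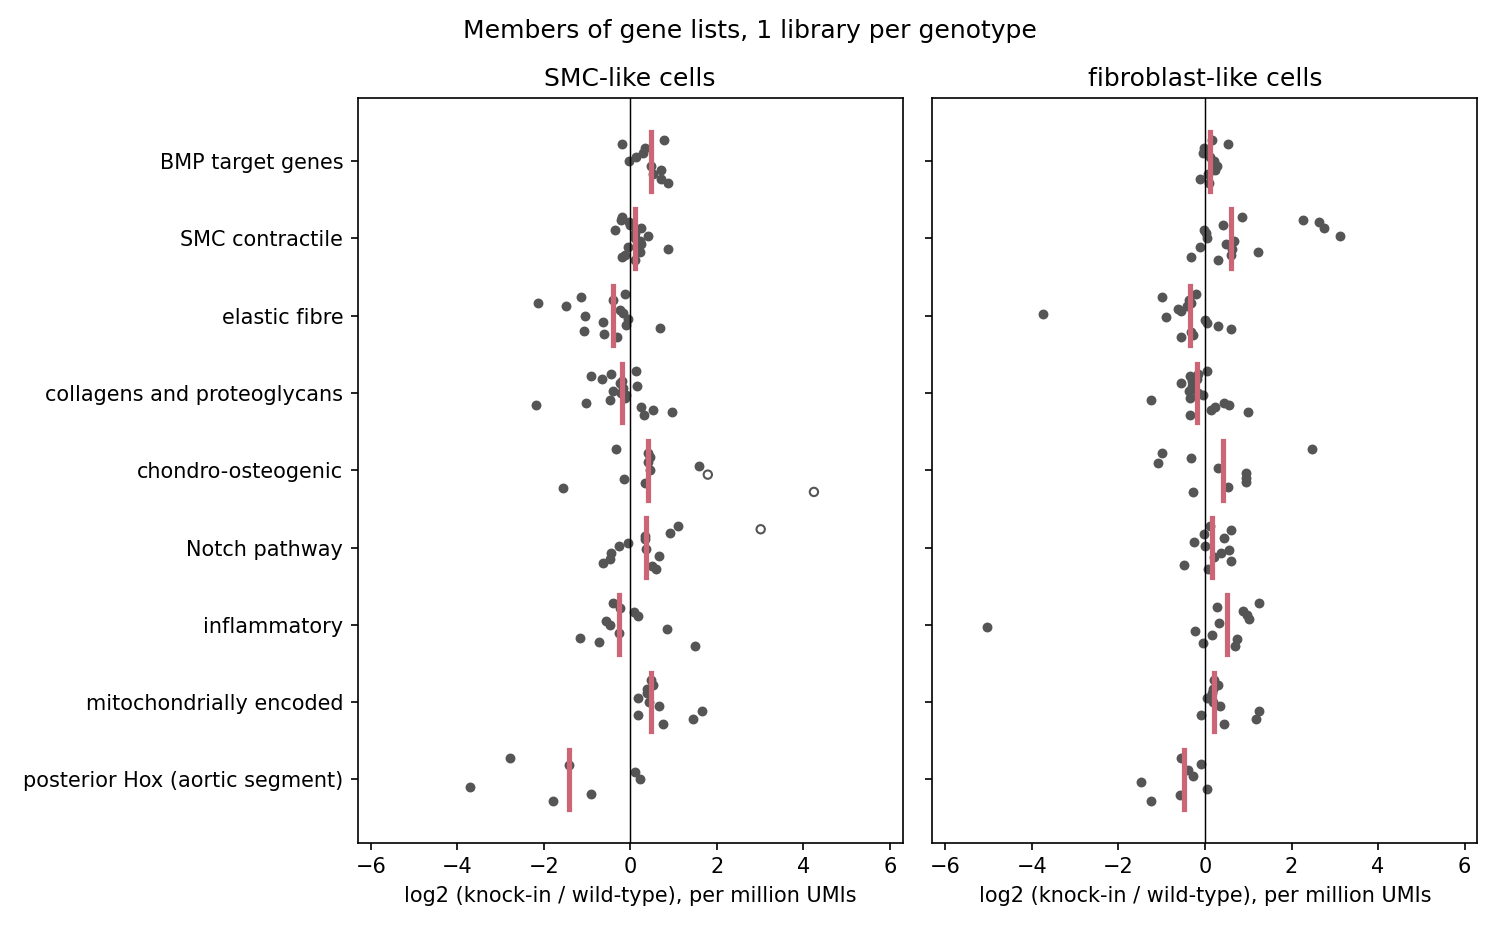
Log2 ratio of knock-in over wild-type CPM for the measured members of 9 gene lists in SMC-like cells (left) and fibroblast-like cells (right), 1 library per genotype. Each point is a gene, hollow where 1 library had 0 UMIs and the ratio rests on the added count, and red lines are list medians; in SMC-like cells the BMP target median is 0.49 and the elastic fibre median -0.39.

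Fibroblast-like cells, which produce collagen and other matrix, showed the same kind of difference in clock genes and lower levels of several matrix genes in the knock-in library. Different clusters held most of these cells, those led by Pex5l (1366 cells) and Tmem100 (771) in the wild-type library and those led by Pex5l (1284) and Entpd2 (1174) in the knock-in library. Dbp was 13.9-fold higher (26.2 against 364 CPM; 3.80, 3.72 to 3.87), with Hlf at 2.35, Nr1d1 at 2.04, Per3 at 1.99 and Bhlhe41, another clock repressor, at 1.98. Npas2 (5400 against 213 UMIs; -3.86, -4.06 to -3.66) and Arntl (-3.69) were lower. The methyltransferase gene Inmt was 7.78-fold higher (26.4 against 205 CPM; 2.96, 2.88 to 3.04), at 3.57 in female and 2.39 in male cells. G0s2, an inhibitor of lipolysis (1.78), the phosphodiesterase Pde4c (2.07) and Ppm1n (1.95) were higher too. Dbp stood at 4.40 in female cells and Pde4c at 2.80 in cells of 8000 to 20000 UMIs. Adipocyte markers had a median of 1.497 in the same cells (percentile 99.6), with 4 of 5 at least 1.5-fold higher, each on 112 UMIs or fewer per library.

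Fibrillin-2, encoded by Fbn2 and typical of developing elastic tissue, was lower in knock-in fibroblast-like cells (28.4 against 2.12 CPM; -3.74, -4.11 to -3.40). The prolactin receptor gene Prlr (-2.71), the kinase gene Nrk (-2.22), Cthrc1 (-1.79), which encodes a secreted collagen-regulating protein, Arhgap20 (-1.82), Cilp (-1.63), Pkdcc (-1.66) and Sytl5 (-1.65) were lower. In the largest fibroblast-like cluster Fbn2 stood at -4.51 and Prlr at -1.03, and Sytl5 stood at -0.25 in cells of 8000 to 20000 UMIs. Tenascin C, encoded by Tnc, stood at -1.78, but at -0.41 with separate clustering and at 0.13 at resolution 1.0 with the first naming limit. Hist2h2aa1 (3.11), Wdr89 (2.03) and Rnaset2a (-2.04) can share reads with near-identical copies and are uncertain. Of 6378 genes 159 were at least 2-fold apart, 76 higher and 83 lower, around a median of -0.09.

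In fibroblast-like cells BMP target genes had a median of 0.12 (percentile 95.5), or -0.04 in female cells, with 0 of 11 measured genes at least 1.5-fold apart. Bambi stood at 0.54, and Id3 at 0.20, or -0.04 in cells of 8000 to 20000 UMIs. The ligand gene Bmp4 stood at 0.39. BMP antagonists had a median of -0.36 (percentile 0.29), or 0.39 in the largest cluster. Follistatin (Fst) stood at -0.72, chordin (Chrd) at -0.36, Twsg1 at 0.44 and Sost at 1.32, or 0.27 in cells of 8000 to 20000 UMIs. Sost had 34 wild-type and 75 knock-in UMIs in female cells, and 111 and 77 in male cells. It is also a leading gene of the largest SMC-like cluster, at 764 CPM there, so UMIs from SMC-like cells are not ruled out.

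Elastic fibre genes had a median of -0.35 in fibroblast-like cells (percentile 0.01), with 4 of 16 at least 1.5-fold lower and 1 higher. Eln stood at 11391 CPM in wild-type and 5679 CPM in knock-in cells, Lox at -0.90, Fbln5 at -0.62, Mfap5 at -0.56, Fbn1 at -0.54 and Ltbp4 at 0.61. In cells of 8000 to 20000 UMIs Eln stood at -0.55 and Lox at -0.45. Collagens and proteoglycans had a median of -0.18, with Col1a1 at -0.35, Col3a1 at -0.30, Dcn at 0.43 and Prelp at 1.00. Col1a2 stood at -0.18, and at 0.00 in cells without a posterior Hox UMI. The chondro-osteogenic median was 0.42 (percentile 99.8), or -0.20 in cells of 8000 to 20000 UMIs. Sox9, a cartilage transcription factor, stood at 0.53 and the bone transcription factor Runx2 at 0.96, while alkaline phosphatase (Alpl), on 740 and 212 UMIs, and Col11a1 (-1.08) were lower.

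Inflammatory genes had a median of 0.50 in fibroblast-like cells (percentile 100), with 6 of 12 at least 1.5-fold higher and 1 lower. The chemokine genes Ccl2 (1.25), Cxcl12 (0.97) and Cxcl1 (0.87) and the adhesion gene Vcam1 (0.69) were higher. The median was -0.39 within female and 1.08 within male cells, and in female cells Ccl2 stood at 0.34 and Cxcl1 at 0.15. Interferon response genes had a median of 0.47 (Ifit3 0.70, Ifitm3 0.47), or 0.14 in cells of 8000 to 20000 UMIs. Wnt pathway genes had a median of -0.0031 (percentile 68.7), with 3 of 15 at least 1.5-fold higher and 4 lower. Among the secreted modulators on this list, Sfrp1 (-1.38) and Frzb (-1.52) were lower, Sfrp2 stood at 0.67 and Rspo3 at 2.08. In the largest cluster Sfrp1 stood at -0.50 and Cxcl12 at 1.57, Frzb stood at -0.85 with separate clustering, and Rspo3 stood at 1.10 in female cells. Dkk2 stood at -1.88, and at 0.03 in the largest cluster. SMC contractile genes had a median of 0.59 (Myh11 3.12, Acta2 0.87). Free RNA also held more of both in the knock-in library, so background is not ruled out for these genes in fibroblast-like cells. Myh11 stood at 1.90 in cells of 8000 to 20000 UMIs, 2.39 in the largest cluster and 4.20 with separate clustering. Acta2 stood at 0.06 in the largest cluster and 1.70 after subtraction of free RNA. That subtraction took Myh11 to 10.4, a value that rests on the added 0.5. The estimated free RNA exceeded the wild-type Myh11 UMIs, of which female cells held 63 and male cells 138. SMC markers stood at 0.61 in fibroblast-like and 1.33 in macrophage or monocyte-like cells. Macrophage markers had a median of -0.66. Posterior Hox genes had a median of -0.48. Imprinted growth genes, a list added after data had been seen, had a median of -0.67 (percentile 0.00), with 9 of 13 at least 1.5-fold lower and 0 higher. They include Dlk1 (-3.76), H19 (-2.78), Mest (-1.45), Peg3 (-1.35) and the growth factor gene Igf2 (-0.99). In the largest fibroblast-like cluster that median was -0.29, with H19 at -0.44, Mest at -0.30, Peg3 at -0.68 and Igf2 at -0.29. Dlk1 stood at -2.90 with separate clustering. In male cells it stood at -5.02 (-10.9 to -3.09), on 118 wild-type UMIs and only 1 knock-in UMI.

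Calcification regulators had a median of -0.0018 in fibroblast-like cells (percentile 65.6), with 3 of 12 at least 1.5-fold lower and 0 higher. Other list medians were -0.07 for BMP ligands and receptors, -0.13 for TGF-beta target genes, 0.23 for modulated SMC genes (Lgals3 1.49, or 0.18 in cells of 8000 to 20000 UMIs), 0.16 for the Notch pathway, -0.13 for hypoxia genes, 0.01 for dissociation stress and 0.20 for mitochondrially encoded genes (mt-Nd3 1.25, mt-Nd4 -0.09). Mesenchymal transition genes stood at -0.01 and anterior Hox genes at -0.12. Endothelial identity genes stood at 0.18, but at -0.07 in female and -0.43 in male cells, and progenitor genes at 0.11, or -0.13 in female cells. The hypoxia median was 0.16 in the largest cluster. Cardiac outflow genes had a median of -0.51 over 6 measured genes, but 0.47 (0.17 to 0.82) in female and -1.12 in male cells, and 0.12 in the largest cluster. List medians within 1 sex or the largest cluster can rest on fewer members than those over all fibroblast-like cells.

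Endothelial-like cells, which line the vessel, were few, so their values describe 64 and 46 cells. Endothelial markers (0.13) and endothelial identity genes (0.07) lay close together in both libraries. Collagens and proteoglycans (1.62) and fibroblast markers (1.74) were higher in knock-in endothelial-like cells. Fibroblast-like cells are the largest class in both libraries, so UMIs from them are not ruled out for these medians. BMP target genes had a median of -0.03. Lymphatic endothelial markers were lower (-2.32), and 6 wild-type and 3 knock-in cells held at least 3 UMIs of them. Mmrn1, a lymphatic marker, had 94 wild-type and 0 knock-in UMIs, which is at least 16.8-fold lower.

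Macrophage or monocyte-like cells, the immune cells of the wall, had a median of -0.00 for their own markers. Progenitor genes had a median of -1.11, with 5 of 6 measured genes at least 1.5-fold lower, and cycling genes one of -0.70, with 7 of 10 lower. Dissociation stress genes had a median of -0.26, with 3 of 17 lower and 14 between. In none of these lists was a gene at least 1.5-fold higher. In the same cells fibroblast markers had a median of -0.31 (percentile 2.29, 4 of 10 lower and 0 higher) and collagens and proteoglycans one of -0.30 (percentile 0.82, 6 of 18 lower and 2 higher). The progenitor list shares Pdgfra and Pi16 with the fibroblast list, and its member Ly6a is a leading gene of a fibroblast-like cluster. UMIs from fibroblasts are thus not ruled out for the progenitor median of macrophage or monocyte-like cells. UMIs of SMC contractile genes stood at a median of 1.22 in these cells, with Acta2 at 52.8 and 114 CPM. In barcodes of 10 to 100 UMIs, which hold free RNA, Acta2 stood at 4054 and 9607 CPM and Myh11 at 370 and 1665 CPM, so these values are read as background. The neutrophil genes S100a8 and S100a9 had 320 and 460 UMIs in the wild-type library and 0 in the knock-in library, at least 71.4-fold and 103-fold lower, and 3 wild-type cells held at least 10 of these UMIs. Of 3041 hemoglobin UMIs in knock-in cells of this class, 3039 lay in 1 cell.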

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

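The tests of the elastic fibre genes by sex and by postnatal stage were chosen before the values they measure were seen, and the other tests in these paragraphs were chosen after the result was seen. Genotype is a group of the design and stays open as an explanation for each pattern, untested with 1 library per genotype.

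SMC-like cells took 42.6% of the knock-in and 8.22% of the wild-type library. A different mix of male and female mice as the whole cause is argued against by a difference of 30.03 percentage points or more within each sex. Fibroblast-like cells per endothelial-like cell were 1.502-fold higher in the knock-in library (1.01 to 2.25), the opposite of what extra fibroblast-like cells alone on the wild-type aortas would give; adventitia left there still cannot be told apart from a difference in the media, because its vessels bring endothelial cells too and the interval holds the 2-fold limit set for excluding it. That criterion was rewritten after values were known: its first form used SMC-like cells per endothelial-like cell, which were 12.2-fold higher (8.06 to 18.6). More complete release of medial cells in the knock-in digestion cannot be told apart from genotype either, since both predict that 12.2-fold ratio.

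BMP target genes had a median log2 ratio of 0.49 in SMC-like cells. A different mix of the sexes is argued against, as the smaller of the medians within female and male cells was 0.31 (0.17 to 0.46). A different mix of aortic segments cannot be told apart from genotype, because the median in cells with a posterior Hox UMI was 0.13 with an interval of 0.06 to 0.56, on 89 wild-type cells. Collection at a different time of day cannot be told apart either, as the median in fibroblast-like cells was 0.12 (0.04 to 0.21), while their clock genes of the Dbp phase had a median of 1.98 against 2.21 in SMC-like cells.

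Eln, with other elastic fibre genes, was lower in knock-in SMC-like cells. Its log2 ratio was -0.86 in the sex with the value nearest 0, which argues against a mix of sexes as the whole cause. After free RNA was subtracted the ratio was -1.15. At the estimated shares of 2.75% and 1.20% the subtraction could hardly move it. The result argues against free RNA only if these shares hold. Within the cluster with most SMC-like cells, 245 of 295 wild-type and 2352 of 2592 knock-in, Eln stood at -1.19. This argues against a different split between SMC-like clusters, but not against a different mix of cells inside the largest. Imprinted growth genes had a median of -0.18 (-0.42 to 0.06) in SMC-like cells. By the criterion chosen beforehand, a median above -0.3 in SMC-like or fibroblast-like cells would exclude wild-type mice at an earlier stage of postnatal growth. The SMC-like median met that criterion, which left out the interval. The interval reaches -0.3, so with this added demand an earlier stage cannot be told apart from genotype. An earlier stage required a median of -0.3 or lower, among the lowest 5% of random lists, in both SMC-like and fibroblast-like cells. Fibroblast-like cells met this (-0.67, percentile 0.00), though their largest cluster alone stood at -0.29, and SMC-like cells did not (percentile 19.96).

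Several ratios had opposite signs in groups of cells, and these differences were not tested. Between female and male cells, Mgp stood at 0.17 and -0.040 over all cells and at 0.48 and -0.021 in fibroblast-like cells. In SMC-like cells Mgp had the same sign in both, at 0.42 and 0.31, while Dcn stood at 0.51 and -1.87. Between SMC-like and fibroblast-like cells, Bambi stood at -0.18 and 0.54, Acta2 at -0.20 and 0.87, and Sfrp2 at -1.02 and 0.67. Dcn stood at -1.02 and 0.43, and mt-Nd4 at 0.18 and -0.092. The estimated free RNA exceeded the Dcn UMIs of SMC-like cells in both libraries, and free RNA held more Acta2 in the knock-in library. Background is thus not ruled out for Dcn in SMC-like and Acta2 in fibroblast-like cells.

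Barcodes below the cell limits also carried signal. In barcodes of 10 to 100 UMIs, Acta2 stood at 9607 CPM in the knock-in and 4054 in the wild-type library, and Myh11 at 1665 and 370 CPM. Barcodes of at least 500 and under 1000 UMIs numbered 228 in the knock-in and 58 in the wild-type library.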

How the results depend on the processing

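The settings for cells of 8000 to 20000 UMIs, the largest cluster of a class, cells with or without a posterior Hox UMI and the first naming limit were chosen after the data were seen, and the other settings before. No paired analysis was possible because each genotype has 1 library. Of the values that answer a comparison, 96 stayed within the counting interval of the reported value (or within 1.5 times a count), 26 moved and 2 turned sign. Of the values of named genes, 1970 stayed, 729 moved and 11 turned sign from a reported interval that leaves out 0. A gene with under 10 UMIs in a setting gave no value there. The cause was not tested for any of the values below. Depth limits genes with few UMIs most, and the wild-type library holds only 295 SMC-like cells.

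The log2 ratio of Mgp over all cells (0.15) was 0.16 with the strict cell filter, 0.21 at 5% mitochondrial UMIs, 0.24 with median-of-ratios scaling, 0.20 with equal weight per cell, 0.14 at 8000 to 20000 UMIs, 0.17 in female and -0.040 in male cells. The difference in the share of SMC-like cells (34.3 percentage points) was 36.0 with the strict filter, 38.3 with the order-of-magnitude rule, 25.2 at 5% mitochondrial UMIs, 44.5 in female and 30.03 in male cells. The difference for fibroblast-like cells (-27.4) was -29.5, -31.8, -20.8 and, in female cells, -36.1 under the same settings in turn. It was -16.5 with separate clustering and -12.2 at resolution 1.0 with the first naming limit.

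A lower count minimum gave 1758 genes at least 2-fold apart in SMC-like cells, in place of 124. The BMP target median (0.49) was 0.13 in cells with a posterior Hox UMI. The contractile median (0.10) was 0.11 with the order-of-magnitude rule, 0.15 with median-of-ratios scaling, 0.047 in female and 0.041 in male cells, 0.14 with and 0.056 without a posterior Hox UMI, and -0.022 at 8000 to 20000 UMIs. The chondro-osteogenic median (0.41) was 0.051 with separate clustering.

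Some named genes turned sign from a reported interval that leaves out 0. In SMC-like cells they were Bambi (0.050) and Comp (-0.15) in male cells and Cytl1 (-0.96) and Dcn (0.51) in female cells. Others were Fst (0.036) without doublet removal and Acan (0.36) in the largest cluster. Within the sex named, counting intervals hold 0 for Bambi (-0.15 to 0.26), Comp (-0.59 to 0.33) and Cytl1 (-2.39 to 1.18), and leave out 0 for Dcn. In fibroblast-like cells the genes that turned sign were Mgp (-0.021) in male cells, Id3 (-0.038) at 8000 to 20000 UMIs and Col1a2 (0.0036) without a posterior Hox UMI. Dkk2 (0.034) in the largest cluster and Tnc (0.13) at resolution 1.0 with the first naming limit did so too. Id3 in SMC-like cells, whose reported interval around -0.03 holds 0, stood at 0.036 at 5% mitochondrial UMIs, 0.019 with median-of-ratios scaling and 0.022 without a posterior Hox UMI.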

Other observations

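The test of the genes around Mgp was chosen before its result was seen, and the test of the clock genes after.

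Clock genes of the Dbp phase were higher in the knock-in library in the 4 classes measured. Genes that peak with Dbp had median log2 ratios of 2.21 in SMC-like, 1.98 in fibroblast-like, 1.45 in macrophage or monocyte-like and 2.48 in endothelial-like cells. Genes that peak with Arntl had medians of -0.99, -1.08, -0.33 and -0.86. The last pair of values lies within the range of 95% of matched random lists, whose lower ends are -0.34 and -0.89. A candidate explanation is that the libraries were collected at different times of day, which requires both lists to differ in opposite directions in the smaller classes too. The smallest Dbp-phase median was 1.45, past the limit of 0.3, but the Arntl-phase median nearest 0 was -0.33, just past -0.3, both limits set after the values were seen. An effect of genotype on the clock would look the same, and the time of collection was not given in the sources used here.

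The cycling cluster, with Mki67, Birc5 and Top2a among its leading genes, held 3.07% of wild-type and 0.443% of knock-in cells. The cluster with pericyte and SMC markers held 0 female and 55 male cells of the wild-type library, and 77 and 83 of the knock-in library. Posterior Hox genes had a median of -1.42 in SMC-like cells, and markers of striated muscle one of -0.61.

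A stretch of chromosome from another strain carried along with the knock-in could alter genes next to Mgp. Of the 50 annotated genes on each side, 19 were measured in SMC-like cells, and 0% of them were at least 2-fold apart (interval 0 to 17.6), against 1.99% of all genes. In fibroblast-like cells the share was 0 of 21 (0 to 16.1), against 2.49%. The measured neighbours were too few for the bound of 10% that would have excluded this, so it stays open.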
